A study of Mus musculus with 6 samples.

How the data were processed

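The material was nuclei from mouse hippocampus at 9.5 months, sorted for PU.1 and sequenced as single-nucleus RNA on the 10x Genomics v3.1 chemistry. There were 6 libraries, 1 per genotype, and each pooled 3 mice. The genotypes combined tau P301S with human APOE4 (P301S/E4), tau P301S without Apoe (P301S/EKO) or human APOE4 alone (E4) with Trem2 present (TREM2+) or deleted (TREM2-). Values by library are given in the order P301S/E4/TREM2-, P301S/E4/TREM2+, E4/TREM2+, P301S/EKO/TREM2+, P301S/EKO/TREM2- and E4/TREM2-. Per the file headers, the deposited matrices held raw UMI counts from Cell Ranger 3.0.1 aligned to mm10, with 31053 features. Of the authors' 3 deposited tables, the marker table held a log fold change and a score per gene, whose base and tool were not stated. The other deposited tables, TERM nuclei against homeostatic nuclei and P301S/E4/TREM2+ against P301S/E4/TREM2-, held log fold changes taken as a score. The p-values in the authors' tables were calculated over nuclei, and the adjusted ones were the p multiplied by the number of genes, with a maximum of 1. TERM is the authors' name for a microglial state. The tables were read only to choose the TERM list and to set values beside those calculated here, and no count, fold change or p in the additive fit came from them. Gene identifiers were matched to GENCODE vM21 (GRCm38), which gave the locations.

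The deposited matrices held 33335 nuclei and 29794968 UMIs, by library 8717000, 5854888, 3705439, 3864709, 3351882 and 4301050. The lowest UMI count of a deposited nucleus differed between libraries. It was 500 in both P301S/E4 libraries and P301S/EKO/TREM2+, 413 in E4/TREM2+, 438 in E4/TREM2- and 224 in P301S/EKO/TREM2-. Nuclei with under 200 detected genes (307 nuclei, all from P301S/EKO/TREM2-) or over 5% of UMIs from mitochondrial genes (1290 nuclei) were left out. Scrublet as implemented in scanpy 1.11.5 was run per library with its own threshold and called 12 of the 31738 passing nuclei, 0.0378%. That share is far under the doublet rate the caller assumes, so the doublet caller has not worked here and doublets remained among the 31726 nuclei analysed. Counts were scaled to 10000 per nucleus and log-transformed. The 2000 most variable genes, leaving out Trem2, Apoe, Xist, Tsix, mitochondrial and Y-linked genes, gave 30 principal components and 15 neighbours. Leiden clustering (leidenalg 0.10.2, seed 1) was run at resolution 1, with 0.5 and 2 as alternatives and no integration across libraries.

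A cluster took the name of another class when at least 3 markers of that class, and at least 50% of them, were raised above 2-fold after 10 CPM were added, and stayed unnamed when several unrelated classes met this. The other classes were border-associated macrophage, monocyte, neutrophil, T or NK cell, B cell, neuron, astrocyte, oligodendrocyte and its precursor, endothelial, mural, fibroblast, and ependymal or choroid plexus cell. A cluster outside blood and myeloid classes that also held microglia markers above 0.5 times the median of the clusters stayed unnamed, and a neuron-like cluster needed at least 0.333 times the median UMI of its own libraries. The remaining clusters were named microglia-like when they held at least 20 nuclei, at least 12 of 23 microglia markers and a median UMI of at most 2 times that of their own libraries. Another class could not hold at least 2, and more than microglia, of the 10 leading genes. These naming rules and the high-UMI rule were set after the clusters and class shares had been seen, but before any differential result. The high-UMI rule left out cluster 6, which was 6.05%, 3.24%, 0.963%, 6.99%, 0.713% and 0.870% of the nuclei of the libraries in the order above. Clusters 0 to 5, 7, 8, 10 and 13 were microglia-like, cluster 9 was named border-associated macrophage-like and cluster 14, with 126 nuclei, neuron-like. The named border-associated macrophage-like share was 3.36%, 2.44%, 3.75%, 1.23%, 1.54% and 4.58%. At resolution 1, clusters 6, 11, 12, 15 and 16 stayed unnamed. The microglia-like nuclei numbered 28859 with 22929246 UMIs. Cluster 5 had the highest Gpnmb, 1511 CPM against 65.4 CPM in the next microglia-like cluster, and is called the Gpnmb-high cluster.

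UMIs of the microglia-like nuclei were summed per library. An additive fit in edgeR 4.0.16 (R 4.3.3, limma 3.58.1) with background and TREM2 genotype as terms used TMM factors, filterByExpr by TREM2 genotype and the quasi-likelihood F test. It covered 11649 genes with 2 residual degrees of freedom, a common dispersion of 0.0155 and a prior of 9.12 degrees of freedom. The contrasts were TREM2- minus TREM2+ over 3 backgrounds, P301S/E4 minus E4 (tau) and P301S/E4 minus P301S/EKO (APOE4) over 2 TREM2 genotypes. A gene was called at a Benjamini-Hochberg adjusted p of 0.05 or less. The standard error (SE) of a log2 fold change was its absolute value divided by the square root of F. A gene called by this test is said to have risen or fallen. The test needs the libraries of different backgrounds to stand in for replicates, so its error holds the spread between pools together with any interaction of TREM2 with background.

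The 19 gene lists were homeostatic microglia, disease-associated microglia (DAM) stages 1 and 2, MHC class I, MHC class II, interferon response, NF-kB and cytokines, complement, cholesterol efflux and storage, cholesterol synthesis, lysosome, ITAM signalling, proliferation, glycolysis, immediate early and heat shock, neuronal and glial transcripts, mitochondrial genome, ribosomal proteins and the authors' TERM markers. The lists, the rule for the TERM list, the tests, the filters and the other settings to be tried were fixed before the data were examined. The TERM list held the 50 genes with the largest positive log fold change in the authors' deposited TERM table at an adjusted p of 0.05 or less, so it was chosen on these same libraries. Lists were tested with camera on the additive fit at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a contrast. The second version rests on the 2 residual degrees of freedom of the fit, so few lists could pass it whatever their correlation. Members were also adjusted over their list alone. For each of 7 genotype pairs, a log2 ratio was taken from effective library sizes with a prior count of 0.5, without a test. Its 95% interval was exact conditional binomial and the intervals of CPM were exact Poisson, so they cover counting error only. A list median used members with at least 20 UMIs in the pair, 1000 Poisson resamples for a 95% counting interval, and a percentile among 10000 random lists matched in 10 bins of expression. A group at 0 UMIs was given a floor of 3 counts, and folds against it are lower bounds.

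Named genes were Trem2, Apoe, Mapt and Prnp, up to 10 called genes per direction and contrast by log2 fold change, the 10 highest and lowest ratios among genes with at least 100 UMIs in 3 pairs, and up to 4 members per list. Pearson r between backgrounds was taken over genes with at least 200 UMIs in every TREM2 pair. Nuclei were thinned to 500 UMIs (alternative 1000), and the share with at least 1 or 3 UMIs of a list was given with a Clopper-Pearson interval. Neuron-like nuclei served as the background of that share.

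The other settings tried were DESeq2 1.42.0, no TMM factor, no expression filter, all nuclei, doublets kept, a minimum of 500 genes, libraries thinned to the same 2736139 UMIs, leaving out 1 library, nuclei of equal weight, total UMIs only, list members with 100 UMIs, genes with 1000 UMIs and Spearman rho. For equal weight, 0.0001 was added to each mean per nucleus and no TMM factor was used. Nuclei were clustered and named again with doublets kept and with at least 500 genes, so these settings also change which nuclei count as microglia-like. TMM was calculated again for every other set of nuclei. Alternatives added after the data had been seen kept the high-UMI cluster, left out the Gpnmb-high cluster, took microglia-like nuclei from resolution 2, or left Trem2 out of the correlation. Departures from the plan were the naming rules, the high-UMI rule, thinned shares of the TERM markers and of Gpnmb and Spp1 alone, and the Poisson resampling. Leaving out 1 library left 1 residual degree of freedom.

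The code was first tested on simulated data, negative binomial counts in the same layout with 200 changed genes. Of genes simulated at log2 fold changes of 1 and 2, the TREM2 contrast recovered 77.3% and 100%, the tau contrast 67.4% and 98.9%, and the APOE4 contrast 76.0% and 97.7%. False calls numbered 6, 18 and 16 among 11276, 11262 and 11287 unchanged genes. Beside them, true calls at log2 fold changes of 1 and 2 numbered 75 and 99 for TREM2, 64 and 89 for tau and 73 and 86 for APOE4. As a share of calls, false ones were thus under 0.05 for TREM2 but above 0.05 for tau and APOE4 in this simulation. No library was a copy of another: chi-square per degree of freedom between pairs of libraries was 3.98 to 29.5. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used. Human APOE and transgene sequence were not among the features as separate genes, the authors' marker table was not used in a calculation, and sorting yields were not analysed here.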

Results

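PU.1-sorted nuclei from the hippocampus of 9.5-month-old mice were profiled by single-nucleus RNA sequencing to ask whether the microglial response to tau P301S with human APOE4 depends on TREM2. There were 6 libraries, 1 per genotype, each a pool of 3 mice: tau P301S with APOE4 (P301S/E4), tau P301S without Apoe (P301S/EKO) and APOE4 alone (E4), each with Trem2 present (TREM2+) or deleted (TREM2-). The deposited matrices held 33335 nuclei and 29794968 UMIs. By library this was 7338 nuclei with 8717000 UMIs in P301S/E4/TREM2-, 6267 with 5854888 in P301S/E4/TREM2+, 5309 with 3705439 in E4/TREM2+, 3723 with 3864709 in P301S/EKO/TREM2+, 5526 with 3351882 in P301S/EKO/TREM2- and 5172 with 4301050 in E4/TREM2-. Over all nuclei the median was 494 detected genes. Microglia-like clusters held 28859 nuclei, and their share in that order was 88.2%, 92.7%, 92.2%, 89.0%, 94.1% and 89.7%, a share that also depends on how clusters were named: it was 96.0% in P301S/EKO/TREM2+ at Leiden resolution 2 and 94.2% in P301S/E4/TREM2- with the high-UMI cluster kept. A genotype had 1 library, so a difference between a pair of libraries has no test, and its interval covers counting error only.

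Trem2, Apoe, Mapt and Prnp were read first in microglia-like nuclei. Trem2 (ENSMUSG00000023992, GRCm38 17:48346401-48354147) was 1165 CPM in P301S/E4/TREM2+, 998 CPM in E4/TREM2+ and 1021 CPM in P301S/EKO/TREM2+, against 578, 410 and 492 CPM in the TREM2- libraries of the same backgrounds, log2 ratios of -1.01, -1.28 and -1.05. Transcripts assigned to Trem2 thus remained in every TREM2- library, at 3712, 1277 and 1397 UMIs, and whether the deleted allele is still transcribed was not analysed here. Apoe (ENSMUSG00000002985, 7:19696109-19699188) was 1180 CPM in P301S/E4/TREM2+ and 777 CPM in P301S/E4/TREM2-, 84.4 and 77.7 CPM in E4/TREM2+ and E4/TREM2-, and 12.5 and 8.80 CPM in P301S/EKO/TREM2+ and P301S/EKO/TREM2-. Mapt (ENSMUSG00000018411, 11:104231390-104332090) was 25.1 and 12.2 CPM in P301S/E4/TREM2+ and TREM2-, 26.8 and 30.3 CPM in P301S/EKO/TREM2+ and TREM2-, and 9.15 and 9.96 CPM in E4/TREM2+ and TREM2-. Prnp (ENSMUSG00000079037, 2:131909928-131938429) was 46.3, 24.3, 42.1, 59.2, 12.9 and 21.5 CPM in the same order. Human APOE and transgene sequence had no features of their own. Whether their reads were assigned to Apoe, Mapt or Prnp was not analysed here.

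**Figure D1:**
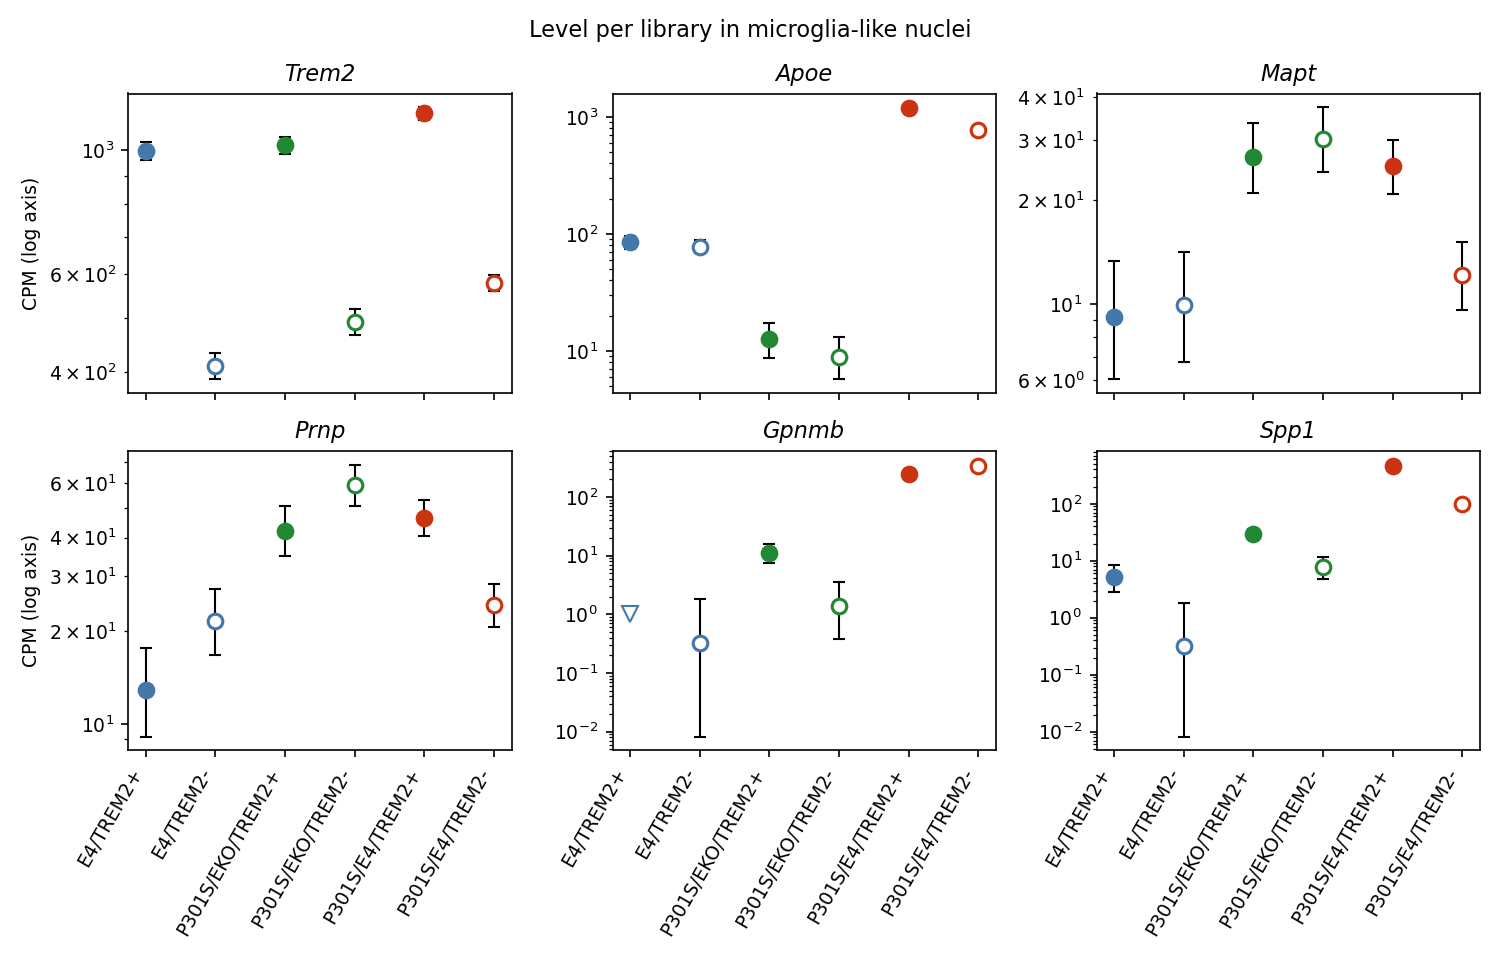
Summed UMIs of microglia-like nuclei as CPM on a log axis, 1 panel per gene and 1 point per library, with 95% Poisson intervals. Filled points are TREM2+, open points TREM2- and a triangle is the upper limit of a count of 0; Trem2 was 410 to 578 CPM in TREM2- libraries, Gpnmb was 342 CPM in P301S/E4/TREM2- and Spp1 100 CPM there against 467 CPM in P301S/E4/TREM2+.

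The first question was what TREM2 deletion does to microglia that carry both tau P301S and APOE4. The P301S/E4 response was present in the TREM2- library, where Trem2 transcripts remained at 578 CPM, but differed in its make-up. Spp1, Lpl, Itgax and MHC class II transcripts were lower, while interferon response and cell-cycle transcripts were higher, and Gpnmb stayed within 2-fold. In P301S/E4/TREM2- over P301S/E4/TREM2+, Itgax (ENSMUSG00000030789, 7:128129547-128150657) had a log2 ratio of -2.31 (153 against 565 UMIs, 95% counting interval -2.57 to -2.05), Spp1 (ENSMUSG00000029304, 5:104435118-104441050) -2.22 (643 against 2228 UMIs), Lpl (ENSMUSG00000015568, 8:68880491-68907448) -1.87 and Ccl6 -1.49. The DAM stage 2 list had a median log2 ratio of -0.32 (counting interval -0.43 to -0.28), with 20 of 23 members below 0. It was -0.52 with at least 500 genes per nucleus. MHC class II had a median of -0.61 (-0.84 to -0.44), with 8 of 8 members below 0, Cd74 at -1.44 and H2-Aa at -1.04. Over all nuclei, which add the border-associated macrophage-like, neuron-like and unnamed clusters, it was -0.30. Among those was unnamed cluster 12, led by H2-Eb1, H2-Ab1, H2-Aa and Cd74, with 122 TREM2- and 34 TREM2+ nuclei. The interferon response list was at 0.51 (0.43 to 0.56) with 23 of 26 members above 0, led by Gbp7 at 1.22, Ifit3 at 0.84 and Rnf213 at 0.81. Proliferation genes were at a median of 1.77 (1.39 to 2.05), or 1.09 over members with at least 100 UMIs, with Mki67 at 3.99 (181 against 8 UMIs, 3.06 to 5.31), Top2a at 2.90 and Knl1 at 2.34. Gpnmb (ENSMUSG00000029816, 6:49036546-49070929) was at 0.47, 2198 against 1176 UMIs, and at -0.16 without the 205 and 16 nuclei named monocyte-like at Leiden resolution 2, a cluster led by Gpnmb itself. Homeostatic genes were at 0.076, or 0.16 with at least 500 genes per nucleus, with Slc2a5 at 0.89 and Tmem119 at 0.76. The complement gene C4b was at 1.30 and the cholesterol exporter Abcg1 at 0.86, the latter within a cholesterol efflux and storage median of 0.19, beside a lysosome median of 0.15 and an ITAM signalling median of 0.28. The highest ratios among genes with at least 100 UMIs were Ccr6 at 5.39, Ahnak at 4.35, Rnf121 at 4.27, Mndal at 4.03, Mki67 and then Cd38 at 3.30. Of these, Ahnak (178 against 6 UMIs) was among the leading genes of the monocyte-like cluster, and those nuclei were not removed here. Ccr6 was also higher in TREM2- in P301S/EKO but lower in TREM2- in E4. Rnf121 was lower in P301S/E4/TREM2+, at 18.0 CPM, than in every other library. The lowest ratios were Gm17430 at -5.77 (3 against 141 UMIs, -8.28 to -4.41), Dkk2 at -4.85, Colec12 at -4.78, Kcnk9 and Cxcl13, each at -3.91, and St8sia6 at -3.87. Gm17430 is annotated as a processed pseudogene inside Colec12, on the opposite strand, and whether they changed separately was not tested. The authors' TERM markers, a list chosen on these libraries and so not independent evidence, had a median of 0.70 (0.49 to 0.85, 36 of 49 members above 0), which was -0.48 with at least 500 genes per nucleus and -0.021 without the Gpnmb-high cluster. At that minimum of genes, a Gpnmb-led cluster of 231 TREM2- and 7 TREM2+ nuclei was named monocyte-like and left out. Mitochondrial transcripts were at 0.46 and neuronal and glial transcripts at -0.54 in the same pair. In the authors' deposited table for this pair, 197 genes passed an adjusted p of 0.05 over nuclei, and of the 193 with at least 100 UMIs here, 192 had the same direction in the same libraries.

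**Figure D2:**
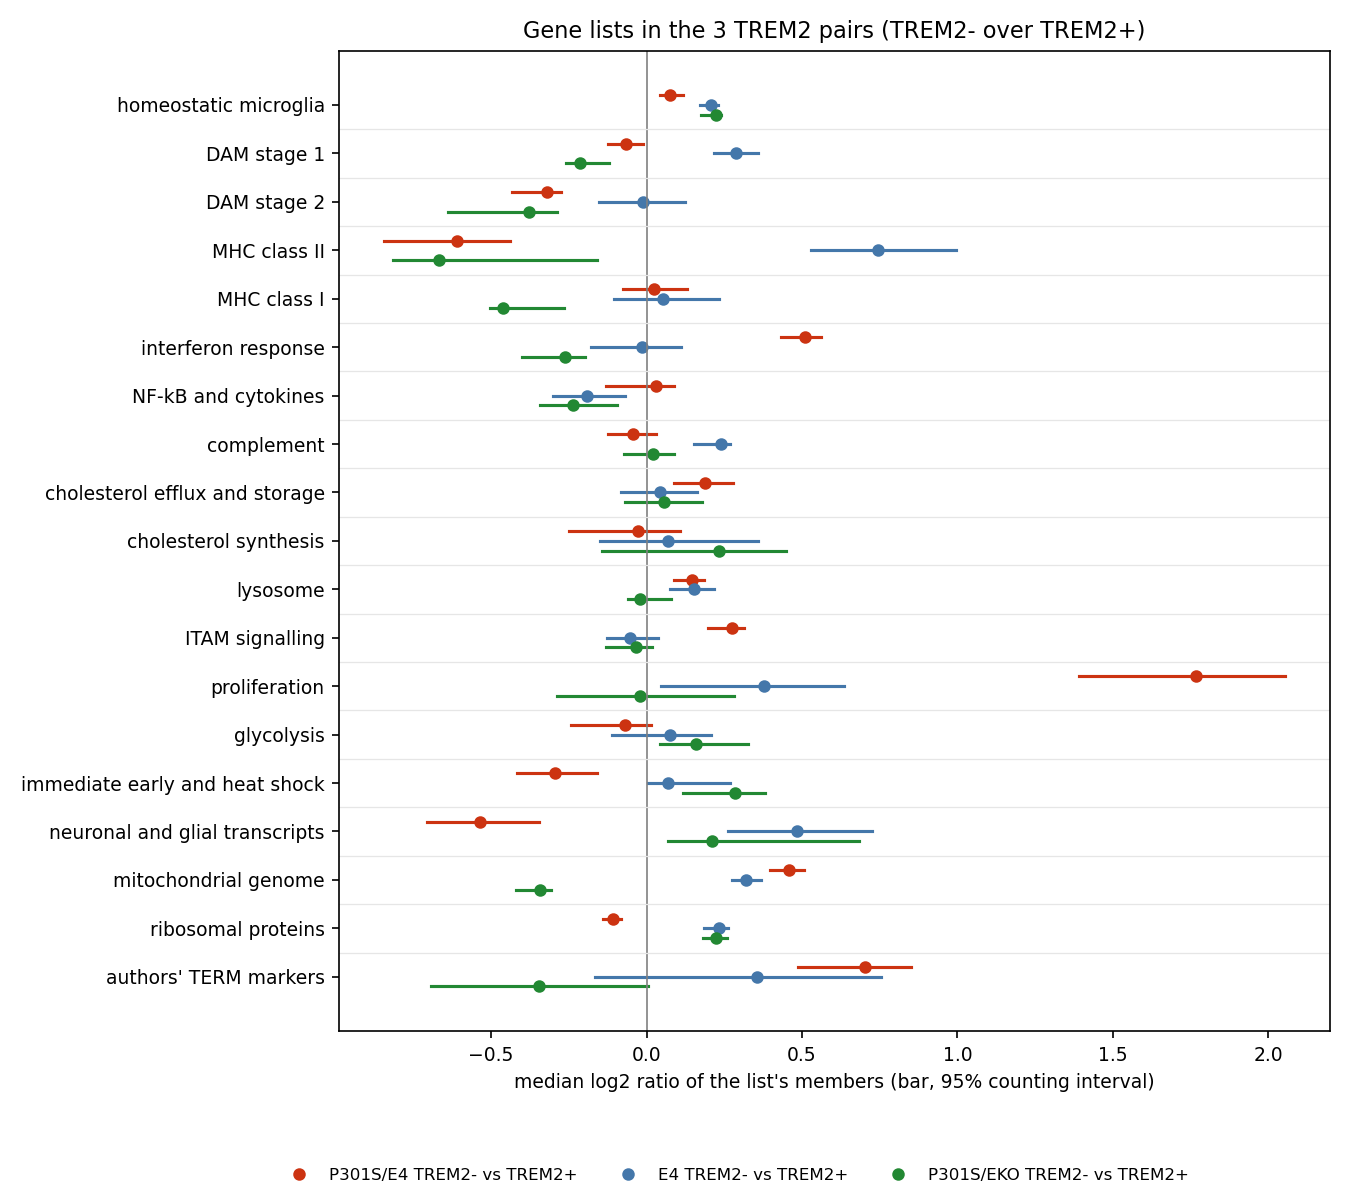
Median log2 ratio of each gene list (TREM2- over TREM2+) in P301S/E4, P301S/EKO and E4 microglia-like nuclei, 1 point per background, with 95% counting intervals. Proliferation stood at 1.77 in P301S/E4 only, and MHC class II was -0.61 in P301S/E4, -0.67 in P301S/EKO (-0.16 at equal weight per nucleus) and 0.75 in E4.

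The same programmes were followed nucleus by nucleus at equal depth. After thinning to 500 UMIs, 43.5% of P301S/E4/TREM2- and 56.8% of P301S/E4/TREM2+ microglia-like nuclei held at least 3 UMIs of DAM stage 2 genes, a ratio of 0.766 (0.739 to 0.795). For MHC class II genes this was 0.389% and 2.46%, a ratio of 0.158 (0.103 to 0.243). That ratio leaves out unnamed cluster 12, led by MHC class II genes, with 122 TREM2- and 34 TREM2+ nuclei. The share was not taken over all nuclei, so how far the ratio depends on this naming was not tested. For interferon response genes the shares were 20.6% and 12.6%, a ratio of 1.64 (1.51 to 1.78). In P301S/EKO/TREM2- and P301S/EKO/TREM2+ the DAM stage 2 share was 21.2% and 32.2% and the interferon response share 9.49% and 14.8%, and in E4/TREM2- and E4/TREM2+ they were 15.4% and 12.9%, and 1.12% and 1.38%. Without thinning, at median depths of 888 UMIs in P301S/E4/TREM2- and 763 UMIs in P301S/E4/TREM2+, the shares were 73.7% and 78.0% for DAM stage 2, 1.47% and 5.53% for MHC class II, and 42.5% and 24.3% for interferon response. Thinning left out 1418 nuclei of E4/TREM2+, 1759 of P301S/EKO/TREM2-, 389 of E4/TREM2- and 0 of the others. Among the 126 neuron-like nuclei, median depth 3001 UMIs before thinning, the shares at 500 UMIs were 1.59%, 0 and 0. Most of these nuclei, 61 and 26, came from E4/TREM2- and E4/TREM2+, where such transcripts were few, and only 16 and 5 from P301S/E4/TREM2- and P301S/E4/TREM2+. Microglia-like nuclei of P301S/E4/TREM2- came mainly from cluster 0 (47.3%), cluster 3 with its interferon response genes (15.4%) and cluster 5, the Gpnmb-high cluster (13.1%), and those of P301S/E4/TREM2+ from cluster 0 (34.5%), cluster 4 with Lpl, Itgax and H2-Aa (21.7%) and cluster 5 (14.8%).

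**Figure D3:**
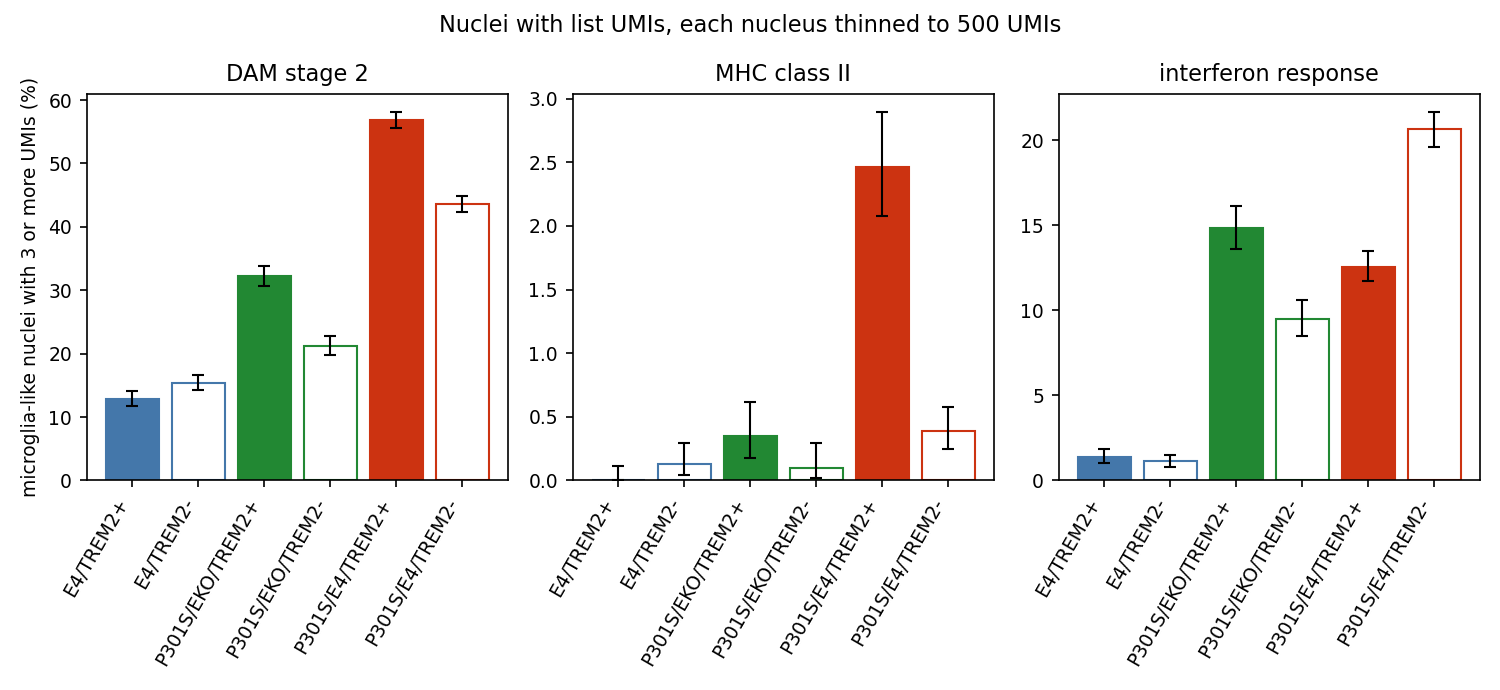
Share of microglia-like nuclei with at least 3 UMIs of a list after thinning to 500 UMIs, 1 bar per library, with exact 95% intervals; filled bars are TREM2+ and open bars TREM2-. DAM stage 2 genes were met in 43.5% of P301S/E4/TREM2- and 56.8% of P301S/E4/TREM2+ nuclei.

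The second question was whether deletion does the same in the other backgrounds. Without Apoe, tau P301S microglia showed the lower Spp1, Lpl and Itgax again, but interferon and MHC class I transcripts were lower too. In E4 mice without tau, Spp1, Lpl and Itgax were lower as well, at few UMIs, while the median of the 16 of 23 DAM stage 2 genes with enough UMIs was level. In P301S/EKO, Spp1 was at a log2 ratio of -1.91 (22 against 83 UMIs, -2.68 to -1.24), Lpl at -1.75, Axl at -1.57 and Itgax at -1.49, with DAM stage 2 at -0.38, DAM stage 1 at -0.21, MHC class II at -0.67 (-0.16 at equal weight per nucleus), MHC class I at -0.46, interferon response at -0.26 and NF-kB and cytokines at -0.24. Rsad2 was at -0.90, Nlrc5 at -0.81 and Crybb1 at 1.39, the last within a homeostatic median of 0.22. In E4, Spp1 was at -3.45 (1 against 15 UMIs), Itgax at -1.75 (5 against 17) and Lpl at -1.23 (15 against 34), with DAM stage 2 at a median of -0.013 (-0.15 to 0.12) and a mean of -0.18, MHC class II at 0.75 (1.14 with at least 500 genes), DAM stage 1 at 0.29 and homeostatic genes at 0.21. Proliferation genes were at -0.020 in P301S/EKO and 0.38 in E4. Mitochondrial transcripts were at -0.34 in P301S/EKO and 0.32 in E4, and neuronal and glial transcripts at 0.21 and 0.48. Microglia-like nuclei of P301S/EKO/TREM2+ were mostly in clusters 0 (33.2%), 1 (22.7%) and 2 (15.96%), of P301S/EKO/TREM2- in clusters 1 (47.4%) and 0 (19.97%), of E4/TREM2+ in clusters 1 (47.7%) and 2 (38.5%), and of E4/TREM2- in clusters 2 (65.3%) and 1 (20.4%). Over 4700 genes the log2 ratios correlated at r = 0.029 between P301S/E4 and E4, -0.0079 between P301S/E4 and P301S/EKO and 0.213 between E4 and P301S/EKO. The first was -0.0003 with all nuclei and -0.035 as Spearman rho, and genes are not independent replicates. Counting error in genes with few UMIs pulls r toward 0 and was not corrected for. Over genes with at least 1000 UMIs, r was 0.089, -0.013 and 0.250 in the same order. An r near 0 therefore does not by itself show that the responses differ.

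The third question was which genes share a response to TREM2 deletion across the backgrounds. The shared response was small and included the DAM genes Spp1, Lpl and Itgax and the matrix gene Ccdc80. It also held genes beside Trem2 on chromosome 17. Across 3 TREM2- against 3 TREM2+ libraries, 16 of 11649 genes changed, of which 2 rose and 14 fell, and 753 had an unadjusted p of 0.05 or less. Ccdc80 (ENSMUSG00000022665, 16:45093402-45128077) fell with a log2 fold change of -2.20 (SE 0.15, adjusted p = 0.00019), Spp1 with -2.20 (SE 0.18, adjusted p = 0.000261), Lpl with -1.76 (SE 0.14), Itgax with -1.97 (SE 0.21), and Trem2 itself with -1.11 (SE 0.10). In P301S/E4, E4 and P301S/EKO the log2 ratios were -2.40, -2.002 and -2.16 for Ccdc80, -1.87, -1.23 and -1.75 for Lpl and -2.31, -1.75 and -1.49 for Itgax. The direction was shared by 3 of 3 backgrounds. A call over these same pairs favours such genes, so this is no further evidence. The other genes that fell were Lox at -3.20, with 0 UMIs in both E4 libraries, Rxrg at -2.28, Etl4 at -2.19, Olfr111 at -2.06, A930002C04Rik at -1.84, Fgr at -1.56 and Ptchd1 at -1.45. Within 1 Mb of Trem2, AI661453 (ENSMUSG00000034382, 17:47436615-47470638) rose with 2.36 (SE 0.24), Mdfi (ENSMUSG00000032717, 17:47815328-47834691) fell with -2.23 (SE 0.27), and Guca1b (ENSMUSG00000023979, 17:47385393-47392967), at 0 UMIs in all TREM2- libraries, was at least 18.8-fold lower (adjusted p = 0.0353). Camk2n1 rose with 0.73 (SE 0.11). Gpnmb stayed at 0.070 (adjusted p = 0.991), Apoe at -0.41 (0.533), C4b at 0.99 (0.0733) and Abcg1 at 0.68 (0.056). Of 23 DAM stage 2 genes, 0 rose and 3 fell, 10 adjusted over the list alone, with a median of -0.45 and a set test at adjusted p = 2.66e-06 (adjusted p = 0.750 with an estimated correlation). Of 22 homeostatic genes none changed singly and 8 rose adjusted over the list alone, with a median of 0.10 and adjusted p = 0.000673 (adjusted p = 0.750 with an estimated correlation). Of 12 proliferation genes 0 rose, 6 adjusted over the list alone, with a median of 0.81 and adjusted p = 0.000106 (adjusted p = 0.765 with an estimated correlation), and Top2a stood at 1.78 (adjusted p = 0.209), led by the P301S/E4 pair. NF-kB and cytokine genes had a median of -0.13 and adjusted p = 0.0260 (adjusted p = 0.750 with an estimated correlation), and 80 ribosomal protein genes 0.11 and adjusted p = 0.000205 (adjusted p = 0.904 with an estimated correlation). Lists past no threshold were TERM (adjusted p = 0.693), complement (0.243), cholesterol efflux (0.184), cholesterol synthesis (0.680), glycolysis (0.720), interferon response (0.714), ITAM signalling (0.680), lysosome (0.118), MHC class I (0.311), MHC class II (0.693), immediate early (0.737), mitochondrial (0.183), neuronal and glial (0.329) and DAM stage 1 (0.720), whose median was -0.02 where its mean was 0.02. The count was 206 without an expression filter (95 up, 111 down), 188 without P301S/E4/TREM2- (105 up, 83 down), 164 without P301S/E4/TREM2+ (97 up, 67 down). It was 151 without E4/TREM2+, 148 without E4/TREM2- and 80 without either P301S/EKO library (42 and 41 up), with 1 residual degree of freedom left.

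The fourth question was how tau P301S alters APOE4 microglia. With tau P301S most homeostatic genes fell and most DAM, interferon response, MHC class I and cholesterol efflux and storage genes rose. As lists none of them passed with an estimated correlation between genes (adjusted p = 0.247 or higher). With 2 residual degrees of freedom few lists could pass that version of the test. Several of the genes that rose had no transcripts in E4. In P301S/E4 against E4, 1779 genes changed, 939 up and 840 down, and 3192 had an unadjusted p of 0.05 or less. The directions were 1102 up and 681 down with no composition factor, and 974 up and 1158 down with all nuclei. Gpnmb rose from 0 and 1 UMIs to 246 and 342 CPM in TREM2+ and TREM2- (log2 fold change 10.54, SE 0.68, adjusted p = 3.75e-06; at least 242-fold in the TREM2+ pair), Adam33 rose by 7.44 (SE 0.35), Spp1 by 6.72 (SE 0.25, adjusted p = 1.71e-07) and Lgals3 by 6.35 (SE 0.54). Genes at 0 UMIs in both E4 libraries that rose were Sh3pxd2b (at least 67.0-fold), Xdh (at least 53.8-fold), Stra6l (at least 53.3-fold), Atp6v0d2 (at least 42.1-fold), Oas1g (at least 39.7-fold), Lox (at least 28.7-fold), Cxcl13 (at least 22.9-fold) and Gbp2b (at least 16.98-fold). Within TREM2- the bounds were only 3.40-fold for Lox and 1.62-fold for Cxcl13, against 28.4-fold and 24.1-fold within TREM2+. Ms4a14, at 0 UMIs in E4 and at least 82.0-fold higher, was left untested by the expression filter. Genes that fell were led by Gpr165 at -5.49 (SE 0.49), Gp9 at -4.12, Gm3558 at -3.67, Gm29927 at -3.52, Serpinf1 at -3.34, Smpdl3b at -3.33, Hlf at -3.30 and Upk1b at -3.25. In the TREM2+ pair, 426 of 8411 genes with at least 100 UMIs were above and 242 below 2-fold. The lowest were Ccr6 at -5.37, Sema4b at -4.19 and Gm31243 at -4.15, but Ccr6 went the other way within TREM2-. Of 22 homeostatic genes 20 fell and 0 rose (21 fell adjusted over the list alone), with Slc2a5 at -2.66 (SE 0.15), Selplg at -1.94, P2ry12 at -1.75 and Tmem119 at -1.69 (median -1.07; adjusted p = 1.42e-14, adjusted p = 0.247 with an estimated correlation). Of 23 DAM stage 2 genes 20 rose and 1, Itgb5, fell (also 20 and 1 adjusted over the list alone; median 2.90; adjusted p = 7.29e-17, adjusted p = 0.318 with an estimated correlation), and of 8 DAM stage 1 genes 6 rose, among them Lyz2 at 2.79, H2-D1 at 1.94 and Ctsb at 1.39 (adjusted p = 9.2e-06, adjusted p = 0.386 with an estimated correlation). Of 26 interferon response genes 24 rose (25 rose and 1 fell adjusted over the list alone), with Ifi44 at 6.24, Oasl2 at 5.10, Ifi204 at 4.46 and Cxcl10 at 4.44 (median 2.73; adjusted p = 8.89e-20, adjusted p = 0.386 with an estimated correlation). Of 11 MHC class I genes 8 rose, with H2-Q7 at 4.33 and Nlrc5 at 3.71 (median 1.18; adjusted p = 1.08e-05, adjusted p = 0.395 with an estimated correlation). Of 7 MHC class II genes Cd74 at 2.46, H2-Aa, H2-Ab1 and H2-Eb1 rose and H2-Oa fell at -1.16 (set test adjusted p = 0.318).

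Lipid and lysosomal genes moved with tau as well. Of 10 cholesterol efflux and storage genes 6 rose, with Plin2 at 2.08 (SE 0.20), Soat1 at 1.34, Abca1 at 1.12 and Abcg1 at 1.11 (median 0.73; adjusted p = 0.00204, adjusted p = 0.361 with an estimated correlation), while 0 of 11 cholesterol synthesis genes changed (adjusted p = 0.753). Of 22 lysosome genes 12 rose and 2 fell, Laptm5 at -0.75 among them (14 and 2 adjusted over the list alone; median 0.57; adjusted p = 0.000175, adjusted p = 0.407 with an estimated correlation). Of 10 complement genes 3 rose and 2 fell, with C3 at 5.97, C4b at 4.02 and Itgam at -0.51 (median -0.12, mean 0.79, test upward at adjusted p = 0.939). Of 16 NF-kB and cytokine genes 5 rose and Il1b fell at -1.04, with Cd83 at 1.97 and Tnf at 1.37 (10 and 3 adjusted over the list alone; median 0.45; adjusted p = 0.0101, adjusted p = 0.385 with an estimated correlation). Of 12 proliferation genes 4 rose, 9 adjusted over the list alone, among them Cenpe at 2.14 and Top2a at 1.49 (median 1.03; adjusted p = 0.000465, adjusted p = 0.428 with an estimated correlation), and its pair median was 0.27 in TREM2+ and 1.56 in TREM2-. Of 13 glycolysis genes 3 rose, Pkm at 0.89 and Tpi1 at 0.81 among them (adjusted p = 0.0266, adjusted p = 0.407 with an estimated correlation). Of 15 immediate early genes 2 rose and 5 fell, with Btg2 at -1.55 and Atf3 at 1.37 (adjusted p = 0.225), and of 15 ITAM signalling genes 1 rose and 1 fell (adjusted p = 0.561). All 19 TERM markers measured rose, a list chosen on these libraries and so not independent evidence (median 4.75; adjusted p = 1.23e-19, adjusted p = 0.273 with an estimated correlation). Of 13 mitochondrial genes 12 fell (median -1.23; adjusted p = 1.23e-08, adjusted p = 0.407 with an estimated correlation), of 13 neuronal and glial genes 5 fell (median -0.76; adjusted p = 0.00539, adjusted p = 0.604 with an estimated correlation; pair medians -0.27, interval -0.61 to 0.14, within TREM2+ and -1.30 within TREM2-), and 3 of 80 ribosomal genes rose (median 0.16; adjusted p = 0.00341, adjusted p = 0.787 with an estimated correlation). List medians within TREM2+ and within TREM2- were -1.07 and -1.12 for homeostatic genes, 2.73 and 3.23 for DAM stage 2, 2.50 and 2.86 for interferon response and 2.59 and 0.98 for MHC class II. With all nuclei MHC class II was at 1.01 and -0.092 and DAM stage 2 within TREM2- at 1.90. MHC class II within TREM2- was at 0.025 with at least 500 genes. TERM medians were 4.44 and 4.79, or 3.19 and 3.83 with genes at 0 UMIs set to their bound and 1.86 and 2.38 with all nuclei. All microglia-like clusters were summed, and those with most nuclei were 0, 3 and 5 in P301S/E4/TREM2-, 0, 4 and 5 in P301S/E4/TREM2+ and 1 and 2 in both E4 libraries. The count was 1070 with DESeq2 and 2904 without P301S/E4/TREM2+.

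The fifth question was what APOE4, as against no Apoe, adds to tau P301S microglia. With APOE4 most DAM stage 2 genes rose, Gpnmb, Spp1 and Igf1 among them, as did some genes of cholesterol efflux and storage, the lysosome and MHC class II, while 6 homeostatic genes fell. As lists none of them passed with an estimated correlation between genes (adjusted p = 0.254 or higher), which few lists could with 2 residual degrees of freedom. No interferon response gene changed. In P301S/E4 against P301S/EKO, 287 genes changed, 176 up and 111 down, and 1954 had an unadjusted p of 0.05 or less. Apoe rose by 6.51 (SE 0.19, adjusted p = 1.61e-08), Gpnmb by 5.55 (SE 0.42, adjusted p = 6.93e-05), Adam33 by 5.07, Ms4a7 by 4.38, Spp1 by 3.89 (SE 0.19, adjusted p = 1.55e-06), Ahnak2 by 3.75, Adgb by 3.69, Igf1 by 3.66, Stra6l by 3.37 and Atp6v0d2 by 3.33. Gpr165 at -3.45, Gp9 at -2.56, Emp2 at -2.27 and Plppr4 at -2.23 fell. Lig4 (ENSMUSG00000049717, 8:9969049-9977686) fell at -2.93 (SE 0.21, adjusted p = 4.25e-05), from 82.5 and 68.3 CPM in the P301S/EKO libraries to 8.57 to 11.3 CPM in the other 4. In the TREM2+ pair, 139 of 8323 genes with at least 100 UMIs were above and 53 below 2-fold. The lowest were Rnf121 at -3.93, Lig4 at -2.86 and Il7r at -2.46. Rnf121 was lower in P301S/E4/TREM2+ than in every other library, and within TREM2- it was higher in P301S/E4 than in P301S/EKO. Of 23 DAM stage 2 genes 15 rose and 0 fell (17 adjusted over the list alone; median 1.12; adjusted p = 1.28e-13, adjusted p = 0.289 with an estimated correlation). Of 22 homeostatic genes 6 fell, 14 adjusted over the list alone, with Selplg at -1.04, Siglech at -0.81 and P2ry12 at -0.77 (median -0.44; adjusted p = 6.5e-08, adjusted p = 0.254 with an estimated correlation). Of 10 cholesterol efflux and storage genes 5 rose, with Plin2 at 1.21, Lipa at 0.87, Soat1 at 0.85 and Abca1 at 0.83 (median 0.55; adjusted p = 0.000355, adjusted p = 0.289 with an estimated correlation). Of 22 lysosome genes 4 rose, 11 adjusted over the list alone (median 0.33; adjusted p = 7.97e-05, adjusted p = 0.580 with an estimated correlation), and of 8 DAM stage 1 genes 3 rose, Lyz2 at 1.47 among them (adjusted p = 0.00127, adjusted p = 0.580 with an estimated correlation). Of 7 MHC class II genes H2-Eb1 at 2.70, H2-Aa at 2.62, Cd74 at 2.01 and H2-Ab1 at 1.94 rose (set test adjusted p = 0.0514). Of 26 interferon response genes none changed (median 0.10; adjusted p = 0.706), with pair medians of -0.34 within TREM2+ (-0.19 with all nuclei) and 0.52 within TREM2-. Of 12 proliferation genes 0 rose, 3 adjusted over the list alone (median 0.81; adjusted p = 0.000621, adjusted p = 0.580 with an estimated correlation), with pair medians of 0.15 and 1.83. The latter was 1.22 with the high-UMI cluster kept. Atf3 at 1.54 and Ccl4 at 0.57 rose, in lists whose set tests stood at adjusted p = 0.445 for immediate early genes and 0.197 for NF-kB and cytokines, and the complement list stood at 0.876. All 15 TERM markers that changed rose, of 19 measured, again not independent evidence (median 2.93; adjusted p = 8.08e-21, adjusted p = 0.254 with an estimated correlation). Of 13 mitochondrial genes 7 fell (median -0.82; adjusted p = 6.08e-08, adjusted p = 0.580 with an estimated correlation) and of 13 neuronal and glial genes Syt1 at -1.41 and Rbfox1 at -1.27 fell (median -0.73; adjusted p = 0.000485, adjusted p = 0.608 with an estimated correlation; pair medians -0.083 within TREM2+, -0.62 there with all nuclei, and -1.33 within TREM2-). Glycolysis genes did not pass (adjusted p = 0.899), their median of 0.09 and mean of -0.02 differing in sign. All microglia-like clusters were again summed, and in P301S/EKO those with most nuclei were 0, 1, 2 and 3 (12.2%) in TREM2+ and 1, 0 and 2 (13.5%) in TREM2-. The count was 147 without the Gpnmb-high cluster, 463 with all nuclei and 935 without an expression filter. On leaving out 1 library it was 1774 without P301S/E4/TREM2+, 542 without P301S/E4/TREM2-, 764 without E4/TREM2+, 752 without E4/TREM2-, 441 without P301S/EKO/TREM2+ and 167 without P301S/EKO/TREM2-.

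**Figure D4:**
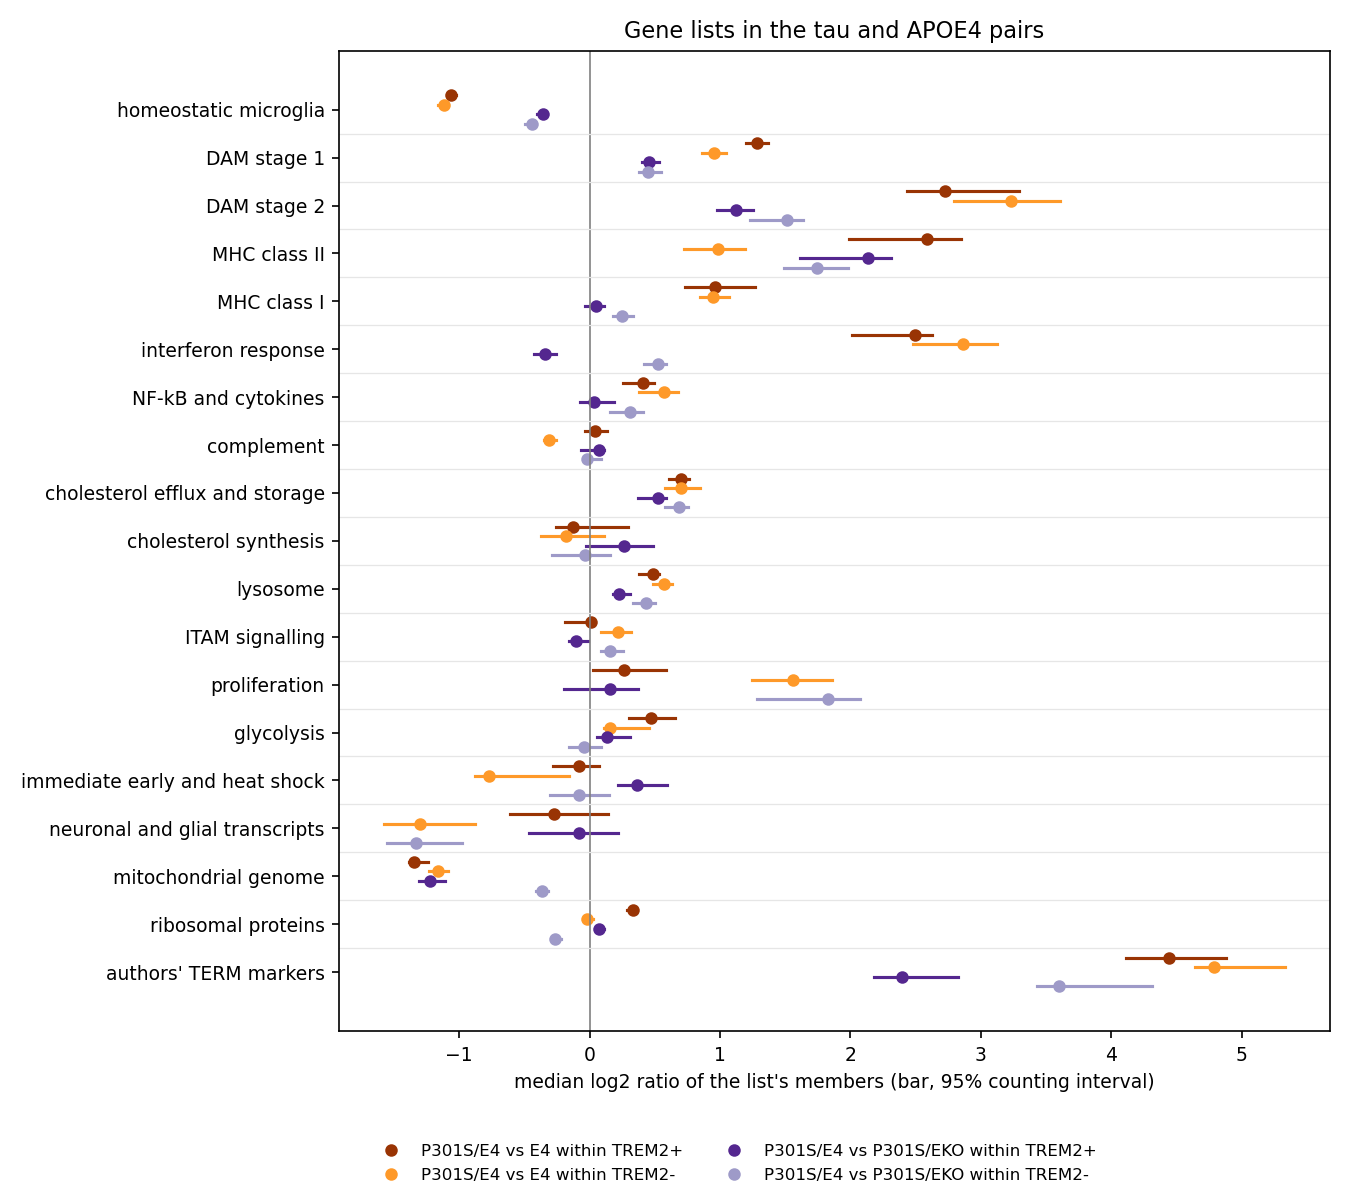
Median log2 ratio of each gene list for P301S/E4 over E4 and for P301S/E4 over P301S/EKO, 1 point per TREM2 genotype, told apart by colour, with 95% counting intervals. DAM stage 2 stood at 2.73 and 3.23 against E4, and interferon response at -0.34 and 0.52 against P301S/EKO.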

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

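The tests on genes beside Trem2, on the fall of homeostatic genes and on the excess of Gpnmb were chosen after the result was seen. A list appears here when its median log2 ratio had opposite signs between groups under the same contrast and each counting interval excluded 0. With 1 library per genotype these differences were not tested.

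For TREM2- over TREM2+, MHC class II was at 0.75 in E4, -0.61 in P301S/E4 (-0.30 with all nuclei) and -0.67 in P301S/EKO (-0.16 at equal weight per nucleus). DAM stage 1 was at 0.29 in E4, -0.067 in P301S/E4 and -0.21 in P301S/EKO. Interferon response was at 0.51 in P301S/E4 and -0.26 in P301S/EKO. Immediate early and heat shock genes were at 0.070 in E4, 0.29 in P301S/EKO and -0.29 in P301S/E4. With at least 500 genes per nucleus the E4 value turned to -0.040 and that of P301S/EKO was 0.026. Neuronal and glial transcripts were at 0.48 in E4, 0.21 in P301S/EKO and -0.54 in P301S/E4, mitochondrial transcripts at 0.46 in P301S/E4, 0.32 in E4 and -0.34 in P301S/EKO, and ribosomal protein genes at 0.23 in E4, 0.22 in P301S/EKO (0.067 with at least 500 genes) and -0.11 in P301S/E4 (-0.035 there). For P301S/E4 over P301S/EKO, interferon response was at 0.52 within TREM2- and -0.34 within TREM2+ (-0.19 with all nuclei), ITAM signalling at 0.16 and -0.10, and ribosomal protein genes at -0.27 and 0.074 (-0.055 and 0.016 with at least 500 genes). A biological difference named by the design, a TREM2 effect that depends on tau or APOE, stayed open as untested.

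Of the 15 genes called with TREM2 deletion besides Trem2, 3 lay within 1 Mb of it: Guca1b, AI661453 and Mdfi. Chance placement of the called genes was argued against, since a permutation test by random draws of tested genes gave p = 1e-05, the smallest possible with 100000 draws, against 0.0219 genes expected there. The other 14 tested genes within 1 Mb had a median absolute log2 fold change of 0.347 against 0.143 for matched lists, the 99.93 percentile. Altered DNA around Trem2, either the deletion itself or flanking sequence kept from the strain in which it was made, had the values it needs and might explain these 3 genes. Which of these it was, and whether loss of TREM2 protein acts on them, stayed open as untested.

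In P301S/E4/TREM2- Gpnmb was higher than in P301S/E4/TREM2+ (log2 ratio 0.47) while Spp1, Lpl and Itgax were lower. Nuclei named monocyte-like at Leiden resolution 2 numbered 205 in P301S/E4/TREM2-, 200 of them in the Gpnmb-high cluster, and 16 in P301S/E4/TREM2+. Without them Gpnmb was at -0.16 (-0.27 to -0.039), against 0.19 (0.11 to 0.26) after 1000 random removals of as many nuclei of that cluster. Their cluster was led by Gpnmb itself, so removing it lowers the ratio by construction, and the excess stayed open. These nuclei do not explain why Gpnmb stays near level. Even after that removal, -0.16 is far from Spp1 at -2.43, Lpl at -1.91 and Itgax at -2.65 in the same nuclei. As for depth, 7.37% of TREM2- and 6.37% of TREM2+ nuclei held Gpnmb at 500 UMIs. Those shares still counted the monocyte-like nuclei, without which Gpnmb in TREM2- went from 2198 to 1308 UMIs. The share at equal depth without these nuclei was not taken, so depth stayed open. A Gpnmb programme that needs TREM2 less than Spp1, Lpl and Itgax do remained a hypothesis, and whether the monocyte-like nuclei are infiltrating cells or a microglial state was not tested.

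Homeostatic genes were lower and DAM genes higher in P301S/E4 than in E4, while mitochondrial transcripts were higher in E4. Neuronal and glial transcripts were at a median of -1.30 (P301S/E4 over E4) within TREM2- and at -0.27 (-0.61 to 0.14) within TREM2+. RNA from other cells in the E4 libraries would dilute microglial transcripts there. The homeostatic median of -1.07 is opposite in sign to such dilution, but it is the fall itself and was no separate test. As a cause of the DAM rise, such dilution would lift every microglial transcript in P301S/E4 alike, by about the 2.90 of the DAM stage 2 list, but 10 microglia markers outside the gene lists had a median of -0.034. A response of microglia to tau stayed open, as did a shift in which microglia the PU.1 gate kept, which might differ between genotypes at a median of -1.07 and was not tested.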

How the results depend on the processing

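The alternatives that kept the high-UMI cluster, left out the Gpnmb-high cluster, took Leiden resolution 2 or left Trem2 out of the correlation were chosen after the results were seen, and all others were planned. Of the values set beside an alternative, 929 stayed the same, 262 moved and 7 turned direction. Moved means out of the counting interval, or for a count of genes by a factor over 1.5. A list median counts as turned only where its counting interval excluded 0 to begin with and the new value left that interval past 0, so other changes of sign count as moved. The values that turned were the TERM median of the TREM2 pair in P301S/E4, from 0.70 to -0.48 with at least 500 genes and to -0.021 without the Gpnmb-high cluster. With at least 500 genes, a Gpnmb-led cluster of 231 P301S/E4/TREM2- and 7 P301S/E4/TREM2+ nuclei was named monocyte-like and so also left out. The glycolysis median in P301S/EKO turned from 0.16 to -0.061 and the immediate early median in E4 from 0.070 to -0.040, each with at least 500 genes. MHC class II in P301S/E4 over E4 within TREM2- turned from 0.98 to -0.092 with all nuclei, which adds the border-associated macrophage-like, neuron-like and unnamed clusters. The correlation of P301S/E4 with E4 turned from 0.029 to -0.00031 with all nuclei and to -0.035 as Spearman rho. Apart from the alternatives whose construction shows it, the cause was not tested. Depth limited genes near 0 UMIs in E4, where folds are lower bounds. A minimum of 500 genes left 1028 of 4690 microglia-like nuclei in E4/TREM2+ and 1140 of 4753 in P301S/EKO/TREM2-, the shallowest libraries. No pairing by mouse was possible because the labels pair no mice across genotypes and each genotype had 1 pool. The additive fit paired libraries by background only.

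Genes changed with TREM2 deletion numbered 16, and 206 without an expression filter, where 20098 genes were tested. Leaving out 1 library, with 1 residual degree of freedom, gave 80 to 188 such genes, with 188 lacking P301S/E4/TREM2-, 164 lacking P301S/E4/TREM2+, 151 lacking E4/TREM2+, 148 lacking E4/TREM2- and 80 lacking either P301S/EKO library. With background in the fit, leaving out either library of a pair leaves the TREM2 comparison to the pairs of the other backgrounds. These are therefore not separate checks per library, and any interaction of the dropped pair leaves the error. The other settings gave 14 to 24. All 16 genes were shared with no composition factor, doublets kept, the high-UMI cluster kept, no Gpnmb-high cluster and Leiden resolution 2, against 14 with DESeq2, 13 with at least 500 genes, 13 with libraries thinned to equal totals and 11 with all nuclei. Tau changed 1779 genes and 1070 with DESeq2, all of them shared, with 1300 to 2904 on leaving out 1 library, the highest lacking P301S/E4/TREM2+. APOE4 changed 287 genes, 935 without a filter, 463 with all nuclei and 147 without the Gpnmb-high cluster. Leaving out 1 library gave 1774 lacking P301S/E4/TREM2+, 542 lacking P301S/E4/TREM2-, 764 lacking E4/TREM2+, 752 lacking E4/TREM2-, 441 lacking P301S/EKO/TREM2+ and 167 lacking P301S/EKO/TREM2-. Other tau settings lay between 1515 and 2453 and other APOE4 settings between 200 and 357. With an estimated correlation between genes 0 lists passed, against 5 for TREM2, 14 for tau and 9 for APOE4 at the preset one. The estimated version rests on 2 residual degrees of freedom, so this does not show that correlation between genes removed the lists. Homeostatic genes in the TREM2 contrast, at an estimated correlation of -0.016, went from a set test p of 0.00014 to 0.053. With at least 1000 UMIs, the correlation was 0.0887 between P301S/E4 and E4 and 0.250 between E4 and P301S/EKO. The ratio of DAM stage 2 shares in P301S/E4 was 0.883 at 1000 UMIs and 0.945 without thinning, and that of MHC class II shares 0.266 without thinning.

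For TREM2- over TREM2+ in P301S/E4, these list medians left their counting interval. With at least 500 genes per nucleus, homeostatic went from 0.076 to 0.16, DAM stage 2 from -0.32 to -0.52, MHC class II from -0.61 to -0.41 and complement from -0.044 to 0.034. Likewise, mitochondrial went from 0.46 to 0.54, ribosomal from -0.11 to -0.035 and TERM from 0.70 to -0.48. With all nuclei, MHC class II went from -0.61 to -0.30, neuronal and glial from -0.54 to -0.72 and ribosomal from -0.11 to -0.19. With called doublets kept, MHC class II went from -0.61 to -0.42. Called doublets numbered only 0 in TREM2- and 5 in TREM2+, but the nuclei were also clustered again. The unnamed cluster led by H2-Eb1 held 122 TREM2- and 34 TREM2+ nuclei in the main setting, and 216 and 243 with doublets kept. With nuclei of equal weight, homeostatic went from 0.076 to 0.15, lysosome from 0.15 to 0.19 and ITAM from 0.28 to 0.32. Likewise, mitochondrial went from 0.46 to 0.53 and ribosomal from -0.11 to -0.029. With members of at least 100 UMIs, proliferation went from 1.77 to 1.09 and immediate early from -0.29 to -0.55. With total UMIs only, homeostatic went from 0.076 to 0.12, DAM stage 2 from -0.32 to -0.27 and lysosome from 0.15 to 0.19. Likewise, ITAM went from 0.28 to 0.32 and ribosomal from -0.11 to -0.063. Without the Gpnmb-high cluster, DAM stage 2 went from -0.32 to -0.45, ITAM from 0.28 to 0.20 and TERM from 0.70 to -0.021.

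For TREM2- over TREM2+ in P301S/EKO, these list medians left their counting interval. Under the minimum of 500 genes, DAM stage 1 went from -0.21 to -0.32, complement from 0.020 to -0.092, cholesterol efflux from 0.057 to 0.18 and cholesterol synthesis from 0.23 to -0.16. Also there, glycolysis went from 0.16 to -0.061, immediate early from 0.29 to 0.026, mitochondrial from -0.34 to -0.45 and ribosomal from 0.22 to 0.067. At equal weight per nucleus, MHC class II went from -0.67 to -0.16, lysosome from -0.020 to -0.067 and ITAM from -0.035 to -0.14. Scaled by total UMIs only, homeostatic went from 0.22 to 0.17, DAM stage 1 from -0.21 to -0.26 and MHC class I from -0.46 to -0.51. Also there, lysosome went from -0.020 to -0.069 and ribosomal from 0.22 to 0.17. Keeping the high-UMI cluster, mitochondrial went from -0.34 to -0.30. Leaving out the Gpnmb-high cluster, TERM went from -0.35 to 0.085.

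For TREM2- over TREM2+ in E4, these list medians left their counting interval. With at least 500 genes per nucleus, homeostatic went from 0.21 to 0.25, MHC class II from 0.75 to 1.14 and immediate early from 0.070 to -0.040. Further, mitochondrial went from 0.32 to 0.18 and TERM from 0.36 to 1.497. With all nuclei, homeostatic went from 0.21 to 0.15, DAM stage 2 from -0.013 to 0.13, mitochondrial from 0.32 to 0.25 and ribosomal from 0.23 to 0.16. With nuclei of equal weight, homeostatic went from 0.21 to 0.15 and ribosomal from 0.23 to 0.17. With members of at least 100 UMIs, DAM stage 2 went from -0.013 to 0.12. With total UMIs only, homeostatic went from 0.21 to 0.15, mitochondrial from 0.32 to 0.26 and ribosomal from 0.23 to 0.18.

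For P301S/E4 over E4 within TREM2+, these list medians left their counting interval. Under the minimum of 500 genes, DAM stage 1 went from 1.29 to 1.38, DAM stage 2 from 2.73 to 3.32 and MHC class II from 2.59 to 1.76. In addition, immediate early went from -0.083 to -0.31, mitochondrial from -1.34 to -1.40 and TERM from 4.44 to 4.12. Over all nuclei, homeostatic went from -1.07 to -0.97, MHC class II from 2.59 to 1.01 and cholesterol synthesis from -0.12 to -0.37. In addition, immediate early went from -0.083 to -0.30, ribosomal from 0.33 to 0.27 and TERM from 4.44 to 1.86. At equal weight per nucleus, homeostatic went from -1.07 to -1.01 and ribosomal from 0.33 to 0.36. Among members with 100 UMIs, interferon went from 2.50 to 1.89. Leaving out the Gpnmb-high cluster, homeostatic went from -1.07 to -0.92, DAM stage 2 from 2.73 to 2.22 and mitochondrial from -1.34 to -1.20. In addition, ribosomal went from 0.33 to 0.37 and TERM from 4.44 to 3.57.

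For P301S/E4 over E4 within TREM2-, these list medians left their counting interval. With at least 500 genes per nucleus, DAM stage 2 went from 3.23 to 2.67, MHC class II from 0.98 to 0.025, complement from -0.31 to -0.25 and lysosome from 0.57 to 0.63. There too, ITAM went from 0.22 to 0.059, mitochondrial from -1.16 to -1.05, ribosomal from -0.023 to 0.10 and TERM from 4.79 to 2.80. With all nuclei, homeostatic went from -1.12 to -0.99, DAM stage 2 from 3.23 to 1.90, MHC class II from 0.98 to -0.092 and interferon from 2.86 to 2.35. There too, complement went from -0.31 to -0.23, cholesterol synthesis from -0.18 to -0.44, glycolysis from 0.16 to 0.048 and immediate early from -0.77 to -0.89. At this setting, neuronal and glial went from -1.30 to -2.07, mitochondrial from -1.16 to -0.97, ribosomal from -0.023 to -0.085 and TERM from 4.79 to 2.38. With called doublets kept, mitochondrial went from -1.16 to -1.07 and TERM from 4.79 to 4.63. With nuclei of equal weight, homeostatic went from -1.12 to -0.91, DAM stage 1 from 0.95 to 1.09, MHC class I from 0.95 to 1.11 and NF-kB from 0.57 to 0.72. There too, complement went from -0.31 to -0.13, lysosome from 0.57 to 0.68, ITAM from 0.22 to 0.41 and mitochondrial from -1.16 to -1.004. At this setting, ribosomal went from -0.023 to 0.13 and TERM from 4.79 to 5.41. With members of at least 100 UMIs, proliferation went from 1.56 to 1.19 and immediate early from -0.77 to -0.92. With total UMIs only, homeostatic went from -1.12 to -0.996, DAM stage 1 from 0.95 to 1.07 and MHC class I from 0.95 to 1.07. There too, NF-kB went from 0.57 to 0.69, complement from -0.31 to -0.19 and lysosome from 0.57 to 0.69. At this setting, ITAM went from 0.22 to 0.34, mitochondrial from -1.16 to -1.04 and ribosomal from -0.023 to 0.10. With the high-UMI cluster kept, complement went from -0.31 to -0.35, mitochondrial from -1.16 to -1.07 and TERM from 4.79 to 4.27. Without the Gpnmb-high cluster, homeostatic went from -1.12 to -0.99, DAM stage 2 from 3.23 to 2.38 and complement from -0.31 to -0.22. There too, mitochondrial went from -1.16 to -1.02, ribosomal from -0.023 to 0.036 and TERM from 4.79 to 2.52.

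For P301S/E4 over P301S/EKO within TREM2+, these list medians left their counting interval. Under the minimum of 500 genes, interferon went from -0.34 to -0.47 and ribosomal from 0.074 to 0.016. Over all nuclei, homeostatic went from -0.36 to -0.31, MHC class I from 0.050 to 0.13, interferon from -0.34 to -0.19 and complement from 0.072 to 0.11. At this setting, neuronal and glial went from -0.083 to -0.62, mitochondrial from -1.22 to -1.07, ribosomal from 0.074 to 0.014 and TERM from 2.39 to 1.79. At equal weight per nucleus, interferon went from -0.34 to -0.24 and ribosomal from 0.074 to 0.035. Scaled by total UMIs only, ribosomal went from 0.074 to 0.036. Leaving out the Gpnmb-high cluster, homeostatic went from -0.36 to -0.29, DAM stage 2 from 1.12 to 0.95 and interferon from -0.34 to -0.22. At this setting, complement went from 0.072 to 0.12 and TERM from 2.39 to 1.956.

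For P301S/E4 over P301S/EKO within TREM2-, these list medians left their counting interval. With at least 500 genes per nucleus, DAM stage 1 went from 0.45 to 0.60, DAM stage 2 from 1.51 to 1.15, MHC class II from 1.74 to 1.28 and interferon from 0.52 to 0.40. Next, complement went from -0.022 to 0.19, proliferation from 1.83 to 1.24, glycolysis from -0.042 to 0.15 and mitochondrial from -0.37 to -0.23. Besides, ribosomal went from -0.27 to -0.055 and TERM from 3.60 to 3.11. With all nuclei, homeostatic went from -0.44 to -0.37, cholesterol efflux from 0.69 to 0.89 and mitochondrial from -0.37 to -0.31. Next, ribosomal went from -0.27 to -0.36 and TERM from 3.60 to 2.66. With called doublets kept, homeostatic went from -0.44 to -0.41, MHC class I from 0.25 to 0.18 and complement from -0.022 to -0.064. Next, proliferation went from 1.83 to 1.23 and mitochondrial from -0.37 to -0.31. With nuclei of equal weight, homeostatic went from -0.44 to -0.34, interferon from 0.52 to 0.62 and mitochondrial from -0.37 to -0.30. With members of at least 100 UMIs, complement went from -0.022 to -0.049 and immediate early from -0.081 to -0.42. With total UMIs only, homeostatic went from -0.44 to -0.38, mitochondrial from -0.37 to -0.31 and ribosomal from -0.27 to -0.21. With the high-UMI cluster kept, MHC class I went from 0.25 to 0.18, complement from -0.022 to -0.066 and proliferation from 1.83 to 1.22. Without the Gpnmb-high cluster, homeostatic went from -0.44 to -0.31, DAM stage 2 from 1.51 to 0.96 and complement from -0.022 to 0.10. Next, mitochondrial went from -0.37 to -0.25, ribosomal from -0.27 to -0.21 and TERM from 3.60 to 1.77.

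At Leiden resolution 0.5, the microglia-like share was 90.4% in P301S/E4/TREM2-, 94.4% in P301S/E4/TREM2+, 91.5% in P301S/EKO/TREM2+ and 95.2% in P301S/EKO/TREM2-. At Leiden resolution 2, the microglia-like share was 89.6% in P301S/E4/TREM2-, 95.1% in P301S/E4/TREM2+, 96.0% in P301S/EKO/TREM2+ and 95.3% in P301S/EKO/TREM2-. With at least 500 genes, the microglia-like share was 82.2% in P301S/E4/TREM2-, 91.9% in P301S/E4/TREM2+, 88.2% in E4/TREM2+, 84.0% in P301S/EKO/TREM2+ and 91.6% in P301S/EKO/TREM2-. With doublets kept, the microglia-like share was 92.8% in P301S/E4/TREM2-, 92.9% in E4/TREM2+ and 95.3% in P301S/EKO/TREM2+. With the high-UMI cluster kept, the microglia-like share was 94.2% in P301S/E4/TREM2-, 95.9% in P301S/E4/TREM2+, 93.1% in E4/TREM2+, 95.9% in P301S/EKO/TREM2+, 94.8% in P301S/EKO/TREM2- and 90.6% in E4/TREM2-.

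Thinned to 1000 UMIs, the share with at least 3 DAM stage 2 UMIs was 79.4% in P301S/E4/TREM2-, 90.0% in P301S/E4/TREM2+, 39.6% in E4/TREM2+, 69.1% in P301S/EKO/TREM2+, 55.8% in P301S/EKO/TREM2- and 44.9% in E4/TREM2-. Thinned to 1000 UMIs, the share with at least 3 MHC class II UMIs was 1.04% in P301S/E4/TREM2-, 7.72% in P301S/E4/TREM2+, 1.56% in P301S/EKO/TREM2+, 0.00% in P301S/EKO/TREM2- and 0.523% in E4/TREM2-. Thinned to 1000 UMIs, the share with at least 3 interferon response UMIs was 45.4% in P301S/E4/TREM2-, 29.5% in P301S/E4/TREM2+, 5.44% in E4/TREM2+, 35.6% in P301S/EKO/TREM2+, 25.7% in P301S/EKO/TREM2- and 5.40% in E4/TREM2-. Without thinning, the share with at least 3 DAM stage 2 UMIs was 73.7% in P301S/E4/TREM2-, 78.0% in P301S/E4/TREM2+, 19.1% in E4/TREM2+, 57.5% in P301S/EKO/TREM2+, 30.4% in P301S/EKO/TREM2- and 31.8% in E4/TREM2-. Without thinning, the share with at least 3 MHC class II UMIs was 1.47% in P301S/E4/TREM2-, 5.53% in P301S/E4/TREM2+, 0.943% in P301S/EKO/TREM2+ and 0.300% in E4/TREM2-. Without thinning, the share with at least 3 interferon response UMIs was 42.5% in P301S/E4/TREM2-, 24.3% in P301S/E4/TREM2+, 2.79% in E4/TREM2+, 26.7% in P301S/EKO/TREM2+, 11.8% in P301S/EKO/TREM2- and 3.35% in E4/TREM2-.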

Other observations

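The comparison of splits was planned, and the genes named here were read after the result was seen. Some genes stood out by library. Rnf121 was at 18.0 CPM in P301S/E4/TREM2+, against 348 CPM in P301S/E4/TREM2-, 97.9 CPM in E4/TREM2+, 275 CPM in P301S/EKO/TREM2+, 233 CPM in P301S/EKO/TREM2- and 296 CPM in E4/TREM2-. Ccr6 was at 56.9 CPM in P301S/E4/TREM2-, 56.3 CPM in E4/TREM2+ and 76.8 CPM in P301S/EKO/TREM2-, and at 1.26, 1.79 and 4.18 CPM in P301S/E4/TREM2+, P301S/EKO/TREM2+ and E4/TREM2-. The division of Ccr6 follows neither tau, APOE nor TREM2. Treml1, which neighbours Trem2, was at 15.9, 12.5 and 7.75 CPM in P301S/E4/TREM2-, E4/TREM2- and P301S/EKO/TREM2-, and at 3.35, 6.10 and 0.714 CPM in their TREM2+ counterparts. Lig4 was at 82.5 and 68.3 CPM in the P301S/EKO libraries and at 8.57 to 11.3 CPM elsewhere, and was also called in the APOE4 contrast. Tnfsf13b, its neighbour on chromosome 8, was at 114 CPM in P301S/EKO/TREM2+ and 68.3 CPM in P301S/EKO/TREM2-, with 37.7 to 73.2 CPM elsewhere.

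The 6 libraries can be split 3 against 3 in 10 ways, and 3 of these, the real one included, gave at least as many genes as the 16 of the TREM2 contrast. The highest other split gave 64 genes, in 2 splits that each part only the P301S/E4 pair. With background in the fit these 2 splits are the same comparison, that of the P301S/E4 pair. Several times the real count there points to a structure of the samples in which that pair differs most, and a TREM2 effect in that background would give the same count. The log2 ratios of genes with at least 100 UMIs had an SD of 0.417 in the P301S/E4 pair, 0.297 in E4 and 0.309 in P301S/EKO. The other splits that part all 3 pairs gave 0, 6 and 1. With 10 splits, no share under 0.05 can be reached.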
